A study of Mus musculus with 8 samples.

How the data were processed

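RNA from the left ventricle with septum of 8 mice, 4 heterozygotes for a knock-in deletion and 4 wild-type littermates, all 12 months old, was hybridised to Illumina bead arrays, 1 per mouse. Genotype and mouse number came from the labels, which call the mice biological replicates. Per the labels, RNA was extracted with a column kit for fibrous tissue with DNase treatment, and biotinylated cRNA was prepared with a commercial amplification kit. Scanner, software and platform version are not given in the sources used here.

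The deposited non-normalized table holds, per the file headers, a mean bead intensity for each of 25697 probes on each array. Its values are linear and already background-subtracted, since between 23.0% and 27.2% of probes per array lay below 0. The deposited detection p-value of each probe, per the file headers, comes in steps of 1 in 798, as ranks among negative controls would give. A table of intensity values that the authors had normalized between arrays was also deposited. Its columns are linear, with medians between 5.01 and 5.04, and keep the rank order of the same mouse's non-normalized column (Spearman 1.00). The authors' method of normalization is not given in the sources used here. That table served as an alternative.

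Intensities were corrected with the normexp model of limma (nec, with detection p-values and an offset of 16), normalized by quantiles between arrays and taken to log2. The offset and normexp pull differences of dim probes towards 0. Quantile normalization removes any shift common to all genes. Probes detected (p under 0.01) on at least 4 of 8 arrays were kept, which left 10547, and the probe with the highest mean stood for each gene, which left 8146 genes. Differences are heterozygote minus wild type on the log2 scale. They were tested with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment at 0.05 and 95% intervals. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9. The test was checked on simulated data with 50 genes changed at each of 4 sizes.

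Gene symbols were matched to the RefSeq gene names of assembly GRCm38.p6. Of 18120 distinct symbols, 12036 were current and 5207 were synonyms of 1 current gene. Another 876 were unmatched or ambiguous and kept as in the file.

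Before the data were examined, 40 gene lists on fibrosis, hypertrophy, ion handling, metabolism, stress, immunity and other cell types were fixed, with a panel of 25 genes. The tests, the alternatives and the rule for named genes were fixed then too. That rule takes the panel and 12 genes per direction that pass with full separation of the genotypes, filled by smallest unadjusted p where fewer pass. Up to 4 members with the smallest p are named from each list described. Some genes that the rule takes are not reported here. Of the lists, 39 had at least 5 measured members and were tested with camera (preset correlation 0.01). Camera with an estimated correlation, fry, and an exact permutation test of list means per mouse were alternatives. Fry tests whether the genes of a list move one way on balance and compares them with no other genes. Over all 35 splits of the mice into 4 and 4, the fits were repeated.

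Alternatives covered normalization, background correction, the authors' normalized values, the detection filter, probe choice, array weights, the mouse number as a block, the eBayes options, the threshold and each mouse left out in turn. Covariates from the adipocyte and atrial lists and the removal of heterozygote 3 with wild type 2 were added after the data were seen. A Y-linked covariate was not run, because these genes did not divide the mice. Xist and 1 probe of Ddx3y were detected on all 8 arrays. Uty was detected on 1, and Eif2s3y, Kdm5d, Usp9y and the other probes of Ddx3y on 0. A chip or scan batch was not analysed here, so a batch effect cannot be examined.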

Results

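Gene expression was measured in the left ventricle, with the septum, of 12-month-old mice on a Swiss Agouti background. The 8 mice comprised 4 heterozygotes carrying a knock-in deletion and 4 wild-type littermates. Each mouse gave 1 Illumina bead array. Between 10094 and 11545 of 25697 probes were detected per array, the largest number in heterozygote 3, and the median deposited intensity of a probe lay between 4.98 and 7.56. Precision is limited by the number of arrays, 4 per genotype.

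The comparison asks how this genotype, with the fibrosis and hypertrophy named in the study's title, is reflected in ventricular transcripts at this age. No gene passed the test between the genotypes.

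Of 8146 genes tested with limma, 0 reached an adjusted p under 0.05, and the smallest adjusted p was 0.984. At an unadjusted p under 0.05 there were 339 genes, 181 higher and 158 lower in heterozygotes, where 407.3 would be expected by chance. All 4 heterozygotes lay on one side of all 4 wild types in 213 genes, or 2.61% of those tested, against 2.86% by chance. The median SE of a log2 difference was 0.18. In simulated data of the same size, with 50 genes changed at each of 4 sizes, noise was drawn independently for each gene. The test recovered 24% of genes changed by 0.5 on the log2 scale, 62% at 1, 88% at 1.5 and 86% at 2. On the real arrays 1 principal component held 42.5% of the variance, so genes varied together. The cutoff also depends on how many genes change at once, so these shares need not hold for this comparison. Counts at the unadjusted threshold rose to 611 without heterozygote 3 and to 581 without heterozygote 2, and no gene passed the adjusted threshold in either case.

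Natriuretic peptide and fetal contractile genes, which are markers of ventricular hypertrophy, did not pass the test. Nppa (atrial natriuretic peptide) differed by 0.00 (95% interval -0.34 to 0.33) and Nppb (brain natriuretic peptide) by -0.06 (-0.50 to 0.38). Myh7, the slow myosin heavy chain, differed by -0.89 (-1.98 to 0.20), and skeletal actin Acta1 by -0.17. With 1 mouse left out Nppb ran from -0.20 to 0.06, Myh7 from -1.325 to -0.634 and Acta1 from -0.43 to 0.06. Myh7 also tended to be lower in mice with higher atrial genes, as described below. Over 8 mice this relation did not pass (r = -0.666, adjusted p = 0.177, exact permutation). Myh6, the fast myosin heavy chain, differed by -0.10 on its brighter probe and by -0.93 on a dimmer probe, so the probes disagree in size. Nppa, Myh6 and Atp2a2 averaged between 14.21 and 14.39 on a scale that ended at 14.61, where differences are compressed. In the hypertrophy and fetal gene list 20 of 27 measured members were lower and 7 higher, with a mean difference of -0.13. Camera gave this list an adjusted p of 0.106, while all 4 heterozygotes lay below all 4 wild types in the list mean (exact permutation p = 0.0286; 0.557 adjusted over 39 lists), and 0 members passed when adjusted over the list alone. That separation was lost with cyclic loess, median scaling and detection on all 8 arrays (exact permutation p = 0.20, 0.914 and 0.0571). Its members with the smallest p were Hk1 (hexokinase) at -0.56, Myh7, Mef2c at 0.18 and Srf at -0.20 (-0.07 without heterozygote 3), the latter a pair of cardiac transcription factors.

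Genes of the extracellular matrix had mostly positive differences that did not pass the test. Col1a1 differed by 0.16 (95% interval -0.45 to 0.78) and Col3a1 by 0.14 (-0.30 to 0.59), the fibrillar collagens of scar tissue. Lox, which cross-links collagen, differed by 0.46 (-0.42 to 1.34), the protease inhibitor Timp1 by 0.48 (-0.31 to 1.26) and the gelatinase Mmp2 by 0.15. Col1a1 became -0.10 and Mmp2 -0.0015 without wild type 4, Col3a1 0.00 and Lox 0.13 without heterozygote 3, and Timp1 0.10 and osteopontin Spp1 0.41 without heterozygote 4. Over the collagens 9 of 11 measured members were higher, with Col4a1 of the basement membrane at 0.35, Col15a1 at 0.31, Col5a1 at 0.17 and Col6a2 at 0.28, and camera gave an adjusted p of 0.0717. Matrix glycoproteins were higher for 25 of 28 members (adjusted p 0.0938 with camera), including Spp1 at 1.10, Nid1 at 0.30 and Ccn4 at 0.27, while the laminin chain Lama2 was at -0.56. Matrix cross-linking genes were higher for 10 of 13 (adjusted p 0.131), with the collagen chaperone Serpinh1 at 0.29, Pcolce2 at 0.21 and Plod3 at 0.18. Matrix proteases and inhibitors were higher for 11 of 15 (adjusted p 0.101), with Adamts5 at 0.48, Mmp14 at 0.41 and Mmp11 at 0.32. With collagens, 0 members of these lists passed when adjusted over the list alone. Without wild type 2 camera called the glycoprotein (0.23, adjusted p = 0.00226), cross-linking (0.24, 0.00395) and protease (0.26, 0.00502) lists, while without heterozygote 3 the means were 0.06, 0.09 and 0.06, and without both mice (chosen after seeing the data) 0.16, 0.20 and 0.17, with cross-linking called (0.0370).

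TGF-beta ligands did not pass the test. Tgfb1 differed by 0.02 (95% interval -0.43 to 0.47), Tgfb2 by 0.10 (-0.25 to 0.45) and Tgfb3 by 0.07 (-0.56 to 0.71), and their target Ccn2 (connective tissue growth factor) by 0.11 (-0.54 to 0.75). The TGF-beta list was higher for 17 of 23 measured members with an adjusted p of 0.0667 (camera) and 0 members passing over the list alone. Its members with the smallest p were Inhbb at 0.38, the stress cytokine Gdf15 at 0.66, Smad2 at 0.23 and Id3 at 0.30. The collagen mean moved from 0.16 to 0.05 without heterozygote 3 and to 0.31 without wild type 2, and camera then gave adjusted p = 0.864 and 0.00153. The TGF-beta mean was 0.07 and 0.20 in the same fits (adjusted p = 0.885 and 0.00502), and with 1 mouse left out Tgfb1 ran from -0.14 to 0.16, Tgfb2 from 0.01 to 0.21, Tgfb3 from -0.07 to 0.39 and Ccn2 from -0.14 to 0.29. Probes for Postn and Col1a2 were detected on 0 of 8 arrays.

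**Figure D1:**
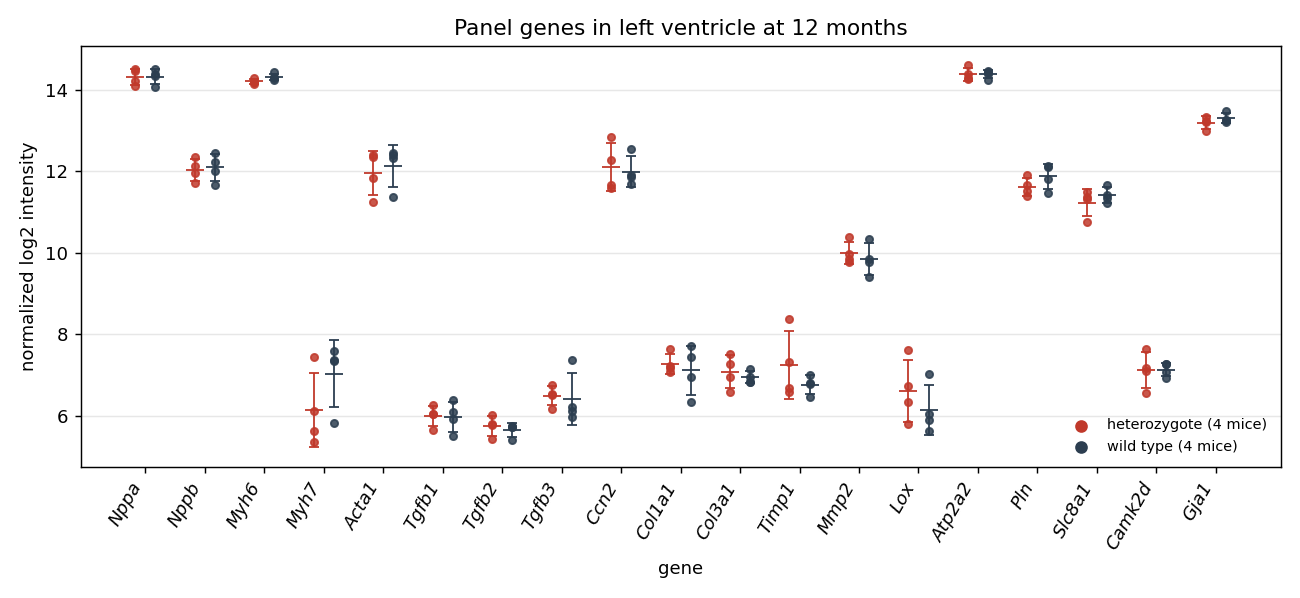
Normalized log2 intensity of the panel genes in each of 4 heterozygotes (red points) and 4 wild types (dark points), with the mean and SD of each genotype. The genotypes overlap for Nppa, Nppb, Col1a1 and Tgfb1, and the means of Myh7 are 6.14 in heterozygotes and 7.03 in wild types.

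Contractile and junctional genes were lower in heterozygotes as groups under camera with its preset correlation. The adult sarcomere list fell, with 18 of 20 members lower and a mean of -0.20 (adjusted p = 0.00139, and 0.686 with an estimated correlation). Its members with the smallest p were Mylk3 (a myosin light chain kinase) at -0.85, troponin I Tnni3 at -0.40, titin Ttn at -0.22 and Ldb3 at -0.62. The intercalated disc and conduction list fell with 16 of 20 members lower (adjusted p = 0.00649, and 0.686 with an estimated correlation). Its members included the desmosomal genes Dsg2 at -0.83 and Dsp at -0.66, Cav3 at -0.51 and the transcription factor Irx3 at -0.53. Dsg2 passed when adjusted over the list alone (adjusted p = 0.0287, limma), and its other detected probe was at -0.46. That adjustment was not corrected over the 39 lists tested, so some passes can arise by chance. Over all genes Dsg2 had an adjusted p of 0.984 (limma). Without heterozygote 3 the sarcomere mean was -0.16 and the disc mean -0.08, and camera still called the sarcomere list (adjusted p = 0.0370) but not the disc list (0.373). The disc call also ended without wild type 4 (adjusted p = 0.118) and with an adipocyte covariate (0.0848, chosen after seeing the data).

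Metabolic lists of the mitochondrion were lower too under the preset correlation. Oxidative phosphorylation fell, with 31 of 43 members lower and a mean of -0.12 (adjusted p = 0.000735, and 0.686 with an estimated correlation). The respiratory chain genes Cox7b at -0.79 and Cyc1 at -0.31 and the ATP synthase subunit Atp5a1 at -0.40 were among the members with the smallest p. Cox7b passed over the list alone (adjusted p = 0.0225, limma), again with no correction over the 39 lists. Over all genes its adjusted p was 0.984 (limma). Fatty acid oxidation fell with 24 of 32 members lower (adjusted p = 0.00446, and 0.686 with an estimated correlation), including Acadl at -0.75, Acaa2 at -0.56 and Decr1 at -0.42, while the coactivator Ppargc1a was at 0.29. Without heterozygote 3 the means were -0.04 for oxidative phosphorylation and -0.12 for fatty acid oxidation, and camera called neither (adjusted p = 0.290 and 0.113), nor fatty acid oxidation without wild type 4 (0.0535) or with array weights (0.123).

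Immune and fat genes were higher as groups in heterozygotes under the preset correlation, and heterozygote 3 was the highest mouse in each list. The interferon response list rose with 21 of 21 members higher and a mean of 0.38 (adjusted p = 7.3e-05 with camera, and 0.686 with an estimated correlation), including the antiviral genes Gbp6 at 0.65, Mx2 at 0.49, Isg15 at 0.78 and Ifit2 at 0.28. Macrophage markers rose with 21 of 22 members higher (adjusted p = 0.00139, and 0.686 with an estimated correlation), among them the chemokine receptor Cx3cr1 at 0.64, F13a1 at 0.40, complement C1qc at 0.65 and Cd14 at 0.46. The inflammatory list rose with 21 of 26 higher (adjusted p = 0.0442, 0.686 with an estimated correlation, 0.0745 with cyclic loess, 0.0967 with median scaling, 0.059 with no detection filter and 0.171 when detected on all 8 arrays), including the chemokines Cxcl14 at 0.78, Ccl12 at 0.55 and Ccl7 at 0.58, while S100a8 was at -0.74. Adipocyte markers rose with 12 of 16 higher (adjusted p = 0.0153, 0.686 with an estimated correlation, 0.0793 with median scaling and 0.171 when detected on all 8 arrays), with leptin Lep at 1.35, Thrsp at 1.10, Acvr1c at 0.61 and Pparg at 0.61. Without heterozygote 3 the means were 0.09 for interferon, 0.02 for macrophage, 0.03 for inflammatory and -0.01 for adipocyte lists, and camera called none of them, while without heterozygote 2 the adipocyte mean was 1.00. With array weights, which counted heterozygote 3 at 0.257, the interferon (0.21, adjusted p = 0.0486) and adipocyte (0.61, 0.0120) lists stayed called, and the macrophage and inflammatory lists did not (0.161 and 0.439), nor with an adipocyte covariate (0.205 and 0.499, chosen after seeing the data).

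Cell cycle genes were higher for 11 of 11 measured members with a mean of 0.34, and camera called this rise (adjusted p = 0.000168). The adjusted p was 0.50 with an estimated correlation. Prc1, a cytokinesis protein, was at 0.92 (SE 0.25), Ccnd2 at 0.41, Ccnd3 at 0.37 and Cdc20 at 0.33. Only 11 of the 31 genes of the list were measured, and without the detection filter 25 of 28 were higher with a mean of 0.20. All 4 heterozygotes lay above all 4 wild types in the list mean (exact permutation p = 0.0286, two-sided, the smallest 4 against 4 can give; 0.557 adjusted over 39 lists), which was lost among the 8 members detected on all 8 arrays (exact permutation p = 0.0571, mean 0.27). Over all 39 lists, camera with its preset correlation called 9, camera with an estimated correlation 0, fry 0 and the exact permutation of list means 0. The last count decides little, because the exact permutation p cannot go below 0.0286. After adjustment over 39 lists, that test could call a list only if many lists reached this floor together. Camera with its preset correlation called 15 lists without heterozygote 1, 15 without wild type 2 and 5 without wild type 4.

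**Figure D2:**
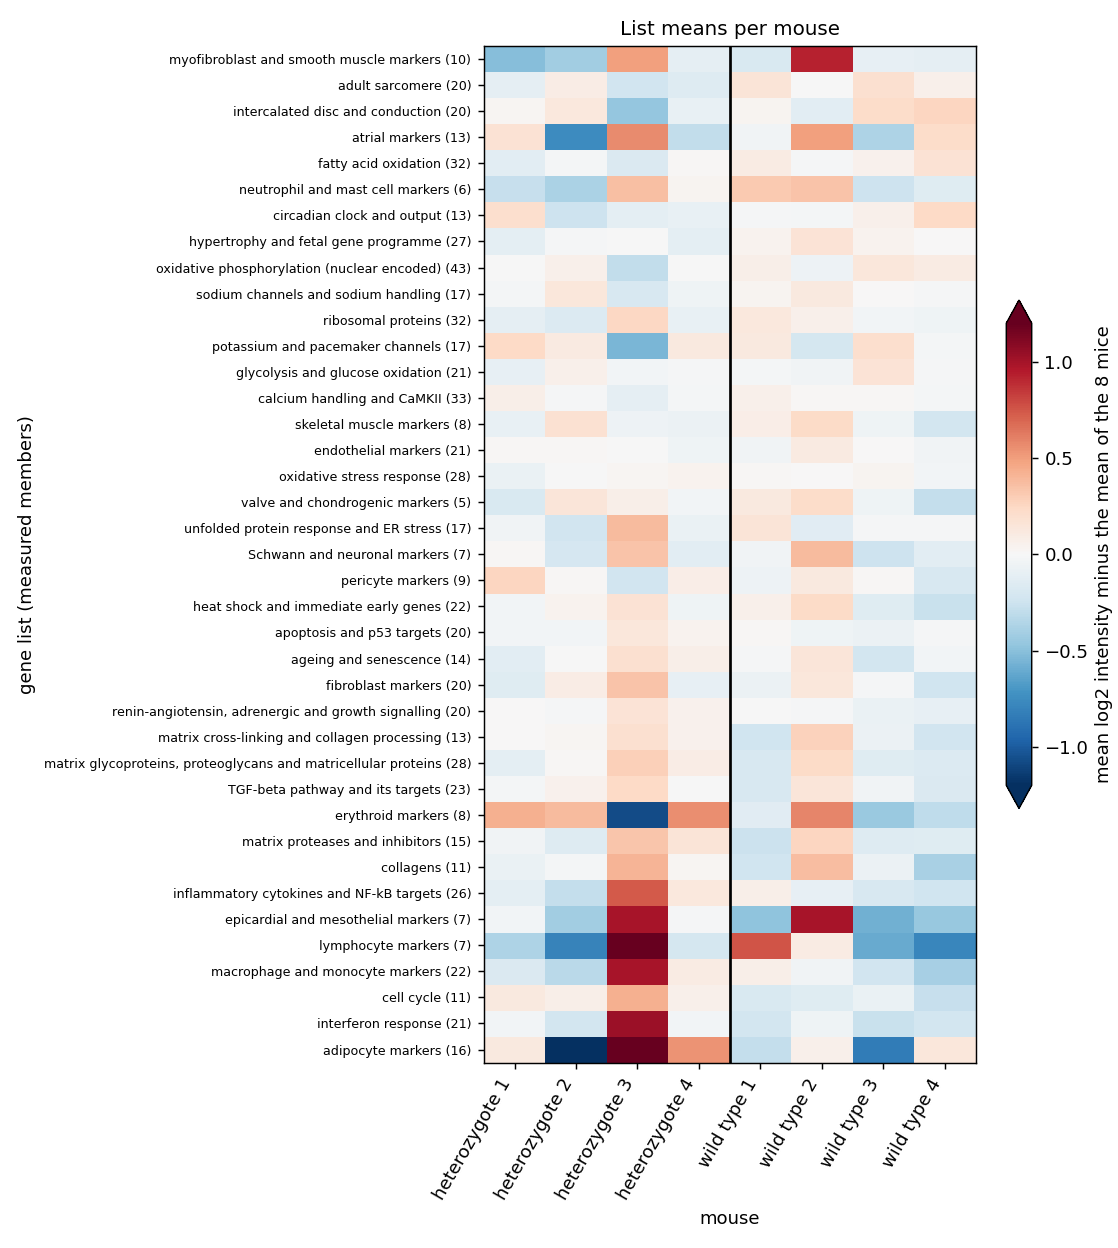
Mean normalized log2 intensity of each gene list in each mouse (columns, heterozygotes left of the line), as the difference from the mean of the 8 mice, with measured members in brackets. Heterozygote 3 is the highest mouse in the interferon (1.03), macrophage (0.99), adipocyte (1.65) and lymphocyte (1.91) lists, and the endothelial list deviates by -0.01 in that mouse. The adipocyte list is also far below the mean in heterozygote 2 (-1.38).

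Sodium, calcium and potassium handling genes did not pass as groups. In the sodium list 11 of 17 members were lower (adjusted p 0.362), with the channel subunit Scn4b at -0.33, Fgf12 at -0.41 and Atp1b2 at 0.21. In the calcium list 20 of 33 were lower (adjusted p 0.517), with the store sensor Stim1 at 0.66, the L-type channel Cacna1c at -0.43, Ppp3ca at 0.29 and Jph2 at -0.46. Atp2a2, the calcium pump, differed by 0.00 (95% interval -0.29 to 0.29), its inhibitor Pln by -0.25, the exchanger Slc8a1 by -0.18, Camk2d by -0.02 and the gap junction gene Gja1 by -0.12. A dimmer Atp2a2 probe, detected on all 8 arrays, was at -0.11. Dimmer Camk2d probes, detected on 6 arrays, were at -0.17 and -0.51. With 1 mouse left out Camk2d ran from -0.19 to 0.17 and Slc8a1 from -0.27 to -0.02. Potassium and pacemaker channels were lower for 11 of 17 (adjusted p 0.458), with Kcnk3 at 0.75 and Kcnip2 at -0.53. Other lists without a camera call included fibroblast markers (18 of 20 higher, adjusted p 0.066, but 0.00399 without heterozygote 1), with Htra3 at 0.36 and Fap at 0.45, and smooth muscle markers (8 of 10 lower, adjusted p 0.106, with a mean of -0.27 that was -0.48 without heterozygote 3, adjusted p 0.00815, and -0.01 without wild type 2), with Tagln at -0.61. Endothelial markers were split, with 9 of 21 higher and 12 lower (adjusted p 0.593), Flt1 at 0.33 and Prox1 at -0.47.

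**Figure D3:**
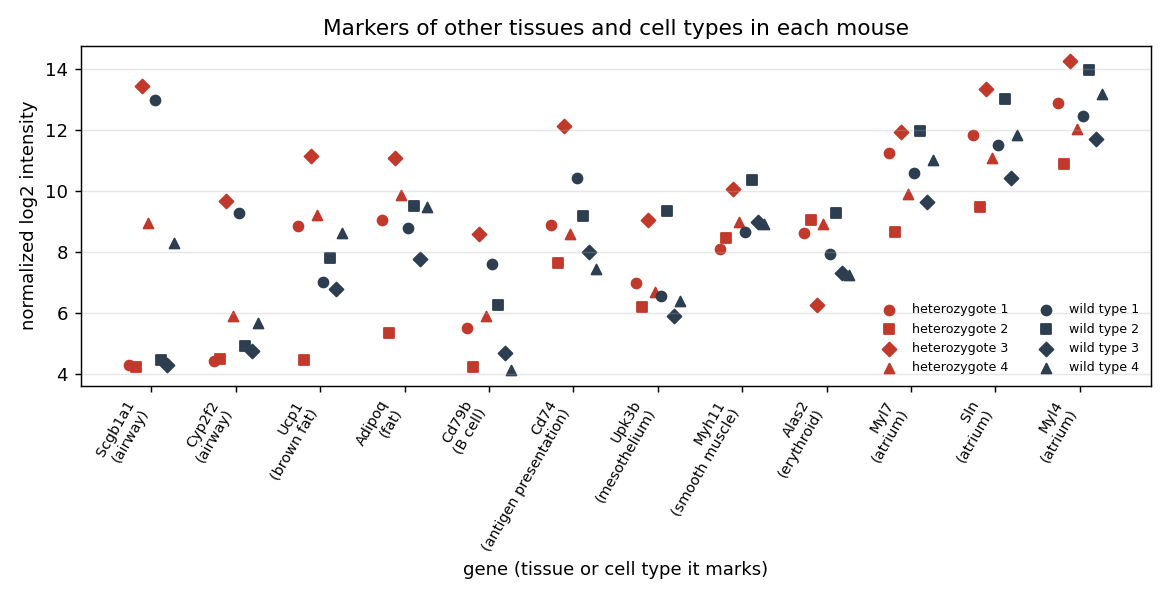
Normalized log2 intensity in each mouse (red heterozygotes, dark wild types, marker shape for the mouse number) of genes that mark airway, fat, immune cells, mesothelium, smooth muscle, erythroid cells and atrium, chosen after their values were seen. Scgb1a1 reaches 13.44 in heterozygote 3 and 12.98 in wild type 1 and was not detected in 4 mice, and the levels do not follow genotype.

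Among single genes with full separation of the genotypes, none passed the test. The 12 with the smallest unadjusted p on the higher side were Kcne4 (0.58), Pdik1l (0.50), Hacd2 (0.60), Stim1 (0.66), Tmem14c (0.79), Eif4ebp2 (0.93), Zmat1 (0.64), Rrp1b (0.44), Zfp292 (0.44), Itga9 (0.96), Zmynd8 (0.53) and Prpf3 (0.47). Kcne4 encodes a potassium channel subunit and Itga9 an integrin. On the lower side were Cox7b (-0.79), Hnrnpa1 (-0.85), Dsg2 (-0.83), LOC622404 (-0.55), Zbtb9 (-0.62), Cast (-0.60), Plaat1 (-1.36), Marchf6 (-1.02), Krr1 (-0.69), Nbr1 (-0.48), Tnni3k (-0.67) and Fam168a (-0.49). Tnni3k is a cardiac kinase and Cast encodes calpastatin. Other detected probes of these genes had the same sign but mostly smaller differences: Tmem14c 0.21 and 0.18, Rrp1b 0.06, Zfp292 0.08, Zmynd8 0.31, Prpf3 0.17, Hnrnpa1 -0.23, Dsg2 -0.46 and Tnni3k -0.68 and -0.49. The smallest SE among these 24 genes was 0.12 (Rrp1b) and the largest 0.33 (Plaat1). With limma each had an adjusted p of 0.984. Several of these genes were dim, on a scale whose lowest value was 4.10. Kcne4 averaged 4.34 and Hacd2 4.49 in wild types, and Cast 4.455 in heterozygotes, while others were bright, such as Tmem14c at 10.12 in wild types.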

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

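The tests of heterozygote 3, of the lists without it and of the cell cycle list were chosen after the results were seen, while the 35 splits were planned. A first form of 4 tests was replaced after its result was known: for the 2 tests of lists without heterozygote 3 it had counted camera calls and then the share of the shift left without its SE, for the cell cycle list it had asked for a call and full separation, and for tissue from outside it had taken members detected in heterozygote 3 alone as well. A test of a shared genotype effect and a test of a distortion of the array were dropped, because their outcome decided nothing. In groups of 4 mice, a value was singled out when its gap to the nearest other mouse, as a share of the whole range, was above the 95% critical value of Dixon. This marked 19 of 172 groups, where chance would give 8.6 if the groups were independent and not selected, and 4 of them lay in heterozygote 3. The groups are neither: lists share genes and mice, and some single genes were chosen for separating the genotypes. The excess over 8.6 is therefore not a test.

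In heterozygote 3 the interferon list averaged 8.13 (others 6.88 to 7.07), the cell cycle list 7.33 (6.96 to 7.02), the erythroid list 6.19 (7.65 to 7.82) and the potassium channel list 5.95 (6.61 to 6.74), in normalized log2 intensity. In wild type 2 smooth muscle markers averaged 9.40 (8.29 to 8.38), epicardial and mesothelial markers 7.40 (5.83 to 5.96) and matrix glycoproteins 8.37 (the lowest other 7.95). Glycolysis averaged 10.50 in wild type 3 (10.29 to 10.32), and skeletal muscle markers 8.39 in heterozygote 2 (8.12 to 8.15). Myh7 was 5.82 and Itga9 4.74 in wild type 2. Wild type 4 had Acta1 at 11.36, Hacd2 at 4.28, Tmem14c at 10.78 and Zmat1 at 5.75. Single values also stood apart for Tgfb2 in wild type 1 (5.40), Stim1 in heterozygote 2 (6.91), Zmat1 in heterozygote 1 (7.06) and Prpf3 in heterozygote 4 (8.66).

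Heterozygote 3 stood apart from the other 7 mice, with a mean correlation of 0.950 with the other arrays against 0.973 to 0.978 for the rest. Tissue from outside the ventricular wall may be present. The 8 lung and thymus markers detected on at least 1 of the other arrays had a median excess of 2.605 over the other mice's median. Over all 16 with a probe it was 0.691. The thymus genes Ptcra and Rag1, among the 8, had an excess of only 0.08 and 0.01. Wild type 1 had Scgb3a1 at 7.16 and Cyp2f2 at 9.30, against 6.51 and 9.70 in heterozygote 3. Its mean correlation with the other arrays was 0.974, so these genes alone do not explain why heterozygote 3 stood apart. The airway gene Scgb1a1 was at 13.44 in heterozygote 3 and 12.98 in wild type 1. Among surfactant genes in heterozygote 3, Sftpd was at 7.93, Sftpc, abundant in lung alveoli, at 5.72, Sftpb at 5.12 and Sftpa1 at 4.86. A genotype effect that varies between mice, an immune response of that animal and the quality of the array stay open and untested.

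The 9 lists called by camera cannot be separated from chance, since 18 of the 35 splits, the real one included, called as many, up to 21 lists. Without heterozygote 3, at most 25.3% of the shift of the interferon, inflammatory, macrophage and adipocyte lists was left, but 1 SE above it passes 50% for all but the interferon list (adipocyte SE 0.62), so that mouse alone may account for them and the test leaves this open. Up to 79.3% was left of the sarcomere, intercalated disc, fatty acid oxidation and oxidative phosphorylation shifts and as little as 35.8%, which leaves that explanation open for these lists, where the first form of the test had counted 1 camera call left of 4. The cell cycle shift of 0.34 was 0.25 (SE 0.045) without heterozygote 3. The value 1 SE below it is over 50% of the full shift, the bound used for the other lists. By that bound the values argue against that mouse alone. The bound was chosen after the results were seen, and a wider one may leave that mouse open as the explanation. A shift of dim genes is argued against as well, since the list mean lay at percentile 100 of 10000 random lists matched on intensity, and a difference in cell composition between the genotypes stays open and untested.

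All 35 splits gave at least as many as the 0 genes past an adjusted p of 0.05, with up to 3 in another split, but no split can give fewer than 0, so this comparison decides nothing. Chance could not be excluded for 2 other counts. For the 339 genes at an unadjusted p under 0.05, 18 splits, the real one included, gave as many, up to 985. Full separation of the groups in at least 2 lists was found in 9 splits, the real one included, up to 6 lists. The split with 985 genes set heterozygotes 1, 3 and 4 and wild type 2 against the rest, and what sets these mice apart was not tested.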

How the results depend on the processing

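Of the 27 alternatives, camera with an estimated correlation, fry and the permutation test cover lists alone and give no gene count. The others gave 0 genes at an adjusted p under 0.05, except the removal of heterozygote 3 with wild type 2 (chosen after seeing the data). That removal gave 1 higher gene, the erythroid anion exchanger Slc4a1 (1.39, adjusted p 0.0286, limma). It took out the lowest heterozygote value of Slc4a1 (4.32, not detected) and the highest wild-type value (6.69), which makes this call. With no mouse left out the difference was 0.45 (unadjusted p = 0.42, limma). The threshold of unadjusted p under 0.01 with a log2 change of 0.58 gave 10 higher and 18 lower. Against 339 genes at an unadjusted p under 0.05, there were 798 with no detection filter (more genes tested), 1041 with array weights, 652 with the atrial covariate, 746 without heterozygote 3 and wild type 2, and 233 to 611 with 1 mouse left out. Median scaling moved the median of all genes from 0.014 to 0.16 and the share above 0 from 53.1% to 77.8%, and values under it are relative to that shift. Same-numbered mice were not more alike: their deviations correlated at -0.22, -0.25, -0.46 and 0.21, against -0.18 to 0.40 for differently numbered mice. Whether the mouse numbers pair the mice cannot be told from these values. The replicate block gave 222 genes.

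Lists called numbered 15 with the atrial covariate, 8 with the adipocyte covariate (both chosen after seeing the data), 8 with array weights, 7 when detected on all 8 arrays, 5 (without wild type 4) to 15 (without heterozygote 1 or wild type 2) with 1 mouse left out, and 0 with an estimated correlation, fry or permutation of list means. The interferon list, 0.38, was not called by these 3 (adjusted p 0.686, 0.808, 0.743) nor without heterozygote 3 and wild type 2 (0.14), and ran from 0.095 to 0.51 with 1 mouse left out. The adipocyte covariate ended the macrophage (0.13), inflammatory (0.10) and disc (-0.11) calls, and array weights the macrophage (0.17), inflammatory (0.16) and fatty acid oxidation (-0.10) calls. The cell cycle list, 0.34, was not called by the same 3 (0.50, 0.239, 0.557), was 0.20 with no filter and ran from 0.25 to 0.38. Of these 3, the permutation test could hardly call any list, since its smallest p is 0.0286 before adjustment over 39 lists. Collagens became called with no filter (0.14), the replicate block (0.16), the mean of probes (0.16) and the atrial covariate (0.21) and without heterozygote 1, heterozygote 4 or wild type 2, and ran from 0.054 to 0.31. TGF-beta became called with the replicate block (0.13), mean of probes (0.12) and atrial covariate (0.15) and without heterozygote 1, heterozygote 4, wild type 2 or wild type 3, and ran from 0.074 to 0.20. Hypertrophy became called with median scaling (-0.16) and mean of probes (-0.17), and ran from -0.15 to -0.09.

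Signs turned, by over 1 SE, for Atp2a2 (-0.15) and Gfra3 (0.12) with median scaling, Gfra3 with cyclic loess (0.24), and Pcolce2 (-0.030) and Mef2c (-0.024) with the mean of probes. They turned for Creld2 (-0.11), Cd3e (-0.10), Coro1a (-0.20), Tnnt1 (0.065), the sodium list (0.011) and the unfolded protein list (-0.16) without heterozygote 3 and wild type 2. With 1 mouse left out Col6a2 ran from -0.050 (without wild type 4) to 0.45. The sign turned without heterozygote 3 for Abcc9 (range -0.29 to 0.19), Cd3e (-0.15 to 0.43), Coro1a (-0.24 to 0.84), Cd52 (-0.45 to 1.00) and the adipocyte list (-0.013 to 1.00), as it did among lists without a call for lymphocyte (-0.33), potassium (0.13), unfolded protein (-0.12), Schwann (-0.10), epicardial (-0.022) and fibroblast (-0.0040) lists. The cause was not tested. Of 3705 values of 187 named genes, 87 changed sign. Signal near background limits dim genes.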

Other observations

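The test of the atrial hypothesis was chosen after the mice were seen to differ, and its threshold was then made stricter, from an unadjusted to an adjusted p. Genes of other tissues varied widely between mice of the same genotype. Scgb1a1, an airway secretory protein, was detected in 4 of 8 mice, at 13.44 in heterozygote 3, 12.98 in wild type 1, 8.97 in heterozygote 4 and 8.30 in wild type 4 (normalized log2 intensity), and Cyp2f2 and Slpi were highest in the same mice, heterozygote 3 and wild type 1. Ucp1, the uncoupling protein of brown fat, ran from 4.47 in heterozygote 2 to 11.15 in heterozygote 3, and Adipoq from 5.36 to 11.10 in the same mice. Cd74 and H2-Ab1, of antigen presentation, and the B cell gene Cd79b were highest in heterozygote 3 (12.13, 11.71 and 8.61), followed by wild type 1 (10.44, 9.94 and 7.63). The erythroid genes Alas2 and Hbb-b2 were lowest in heterozygote 3, at 6.26 and 5.58. Upk3b of mesothelium and Myh11 of smooth muscle were highest in wild type 2, at 9.36 and 10.36.

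Remaining lists had no camera call in the main fit, and several were called in other fits. Lymphocyte markers were higher for 7 of 7 members (adjusted p 0.496) with a mean of 0.27, which was -0.33 without heterozygote 3. Erythroid markers were higher for 7 of 8 (0.568), with a mean of 0.15 that was 0.53 without heterozygote 3 (adjusted p 0.00815, camera), 0.62 with array weights (0.0063) and -0.01 without heterozygote 4. Epicardial markers were higher for 7 of 7 (0.189), with a mean of 0.26 that was 0.64 without wild type 2 (adjusted p 0.00153, camera) and -0.02 without heterozygote 3. Atrial markers were lower for 11 of 13 (0.163), with a mean of -0.15 that was -0.37 without heterozygote 3 (adjusted p 0.00815, camera), -0.36 with the adipocyte covariate (0.000735) and 0.07 without heterozygote 2. Ribosomal proteins were lower for 21 of 32 (0.172), with a mean of -0.06 that was -0.15 without heterozygote 3 (adjusted p 0.000212, camera), -0.10 with array weights (0.0120) and -0.01 without heterozygote 2. Neutrophil and mast cell markers were lower for 4 of 6 (0.496) and clock genes for 8 of 13 (0.163, and 0.0224 without heterozygote 1). Signalling genes were higher for 13 of 20 (0.210), heat shock genes for 15 of 22 (0.518), apoptosis genes for 12 of 20 (0.458), ageing genes for 8 of 14 (0.915) and pericyte markers for 6 of 9 (0.568). Glycolysis genes were lower for 12 of 21 (0.568) and skeletal muscle markers for 5 of 8 (0.858). The oxidative stress (0.568), unfolded protein (0.915), valve (0.974) and Schwann cell (0.969) lists had medians, means and camera directions that differ in sign. The lung and thymus list had too few measured genes to test.

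The atrial genes Myl4, Myl7 and Sln spanned at least 10.2-fold, 9.92-fold and 14.8-fold between mice (the highest Myl4 value lies where the scale is compressed), highest in heterozygote 3 and wild type 2 and lowest in heterozygote 2. A candidate explanation is a varying share of atrial tissue in the samples, under which genes of the ventricle would be lower where atrial genes are higher. Over 8 mice the mean of 6 ventricular genes had r = -0.777 with the atrial mean (exact permutation p = 0.0227, adjusted 0.0795 over 7 relations) and rho = -0.69 (exact p = 0.0694, adjusted 0.243), and r = -0.718 without the 2 farthest mice, so the test leaves the hypothesis open. Irx5 alone had r = -0.859 (exact permutation p = 0.00273, adjusted 0.0191) and rho = -0.934 (exact p = 0.00169, adjusted 0.0118), while Hey2 had r = -0.06 and Myl2, near the top of the scale, 0.32. Myh7 had r = -0.666, Irx3 -0.612 and Irx4 -0.581 (each adjusted 0.177, exact permutation). Without the 2 farthest mice Myh7 had r = -0.437. With genotype as a term, the mean had r = -0.903 (exact permutation p = 0.0104 over 576 orders within genotypes, adjusted 0.0365), and this form was added after the first was known. In that form Irx5 had r = -0.874 and Myh7 -0.867 (both adjusted 0.0365, exact permutation). Irx3 had -0.815 (0.0547), Irx4 -0.665 (0.194), Hey2 -0.07 (0.858) and Myl2 0.465 (0.259). The ventricular genes spanned unequal ranges between mice: 4.70-fold for Myh7, 3.82-fold for Irx5, 3.56-fold for Irx3 and 2.73-fold for Irx4. Hey2, dim at 4.84 to 5.23, spanned 1.31-fold, and Myl2 1.29-fold. Whether a varying share of atrial tissue could give such unequal ranges was not tested.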
